A study of Mus musculus with 14 samples.

How the data were processed

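Poly-A RNA from adult mouse neural stem and progenitor cells was sequenced in 14 libraries that fall into 4 groups. The first pair of groups held quiescent cells grown with BMP4 (4 libraries) and proliferating cells grown with FGF and EGF (4 libraries). The second pair held cells given a GFP virus (3 libraries) and cells given a Cre-GFP virus to delete Yme1l (3 libraries). The 2 pairs were quantified by the authors in separate tables, and each gene's level was tested only between groups of the same table, while fold changes, library totals and the trend with GC content were also compared across the tables. Each sample's group came from the labels, which do not state whether replicates are separate animals or cultures. The p-values therefore measure the spread between these samples, which may be technical.

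The authors deposited salmon gene tables, and the submitters' notes give GRCm39 as the genome build and DESeq2 1.30.1 in R 4.0.3 for their test. The main measurement was the deposited table of estimated counts (expected counts per gene), rounded here to whole numbers. The authors also deposited estimated counts scaled from TPM, length-scaled counts, TPM values (length-normalised transcript abundance) and transcript counts. The deposited test table holds log2 fold changes with standard errors and adjusted p-values. The transcript counts were used only for Yme1l1. Gene coordinates are those of the deposited table. GC content was taken by gene ID from transcripts of an earlier mouse annotation, which covered 99.9% of the tested genes.

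Counts were tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM normalization, filterByExpr by group and a robust quasi-likelihood fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are given as counts scaled by the TMM-adjusted library size (CPM), as mean ± SD. Log2 fold changes carry a standard error computed as the absolute log2 fold change over the square root of the F statistic. Folds against a group with no counts were computed as bounds from 3 counts over the group. For genes with 1 to 3 counts in a group, the ratio of counts carries an exact 95% interval. Bounds and intervals cover counting error only, since the reads carry no molecular identifiers.

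The comparisons, the tests, 41 gene lists and the rule for naming genes were fixed before the data were examined. The named genes were Yme1l1, the 8 rising and the 8 falling genes with the largest fold change in each comparison, up to 3 members of each list, and 5 genes per direction shared by both comparisons. Genes taken by fold needed a mean of at least 5 CPM, no overlap between the groups and a symbol that is not that of a predicted gene. Every measured member of a list with 8 or fewer could be named.

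Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and adjusted over the 39 lists (quiescent) or 38 lists (Yme1l) tested. Camera asks whether a list moved relative to other genes. The lists covered DNA replication, mitosis, cyclin-dependent kinase inhibitors together with genes of exit from the cycle, and quiescent and activated stem cell markers. They also covered markers of 6 other cell types (neuroblasts, astrocytes, oligodendrocytes, microglia, vessels, ependyma), BMP, ERK and Notch signalling and immediate early genes. The rest were lipid, sterol, sugar, nucleotide and one-carbon metabolism, mitochondrial functions, both ribosomes, stress responses, lysosomes, matrix and hypoxia. Sex-chromosome markers were read as a check. Genes that followed quiescence were tested as sets in the Yme1l comparison, and the fold changes of both comparisons were correlated across genes.

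On simulated counts with the depth and spread of these libraries, the gene test recovered 84.6% of genes changed 2-fold in the quiescent design and 89.6% in the Yme1l design. At 1.5-fold it recovered 59.7% and 77.3%. Of the calls on simulated data, 4.2% and 3.3% were unchanged genes. The list test called the list moved by 1.3-fold in both designs and 0 of 38 unmoved lists. For the gene test the simulation changed 200 genes, with the same folds up and down. In the data 65.4% (quiescent) and 51.6% (Yme1l) of tested genes were called. The simulated recovery and error rates therefore do not cover changes this widespread, or a single library that stands apart. The simulation drew each gene independently and filled the lists at random. Its list result therefore does not cover lists whose genes vary together, such as the G2/M list in the KO (estimated correlation 0.892).

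The alternatives were size factors by RLE, library size alone, DESeq2 1.42.0, limma on log2(TPM + 1), no filter on low counts, a filter of 1 CPM in every library of a group, all 14 libraries in one fit, a 2-fold threshold, a replicate block, leaving out each library, camera with an estimated correlation, and fry. Removing each library's trend with GC content, TPM-scaled counts and, for the quiescence sets, an estimated correlation and leaving out each quiescent or proliferating library were chosen after seeing the data. The length-scaled counts differed from the gene counts by at most 0.055, so that alternative moved nothing. No sample was left out.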

Results

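RNA sequencing counts were available for 14 libraries of adult mouse neural stem and progenitor cells in 4 groups. The quiescent libraries (BMP4, n = 4) held 6475099 to 8797750 counts and the proliferating libraries (FGF and EGF, n = 4) held 8331999 to 8992709. The GFP control libraries (n = 3) held 9226080 to 10320736 counts and the Yme1l KO libraries (Cre-GFP virus, n = 3) held 9053124 to 9490756. The labels of the KO libraries also name a wild-type mouse, and the level of the target gene was therefore read first.

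Yme1l1 (ENSMUSG00000026775, chromosome 2, 23046381 to 23089272) encodes YME1L, an ATP-dependent protease of the inner mitochondrial membrane. Its level fell from 127 ± 7.49 CPM (SD, n = 3) in the GFP control to 24.7 ± 1.61 CPM (SD, n = 3) in the KO. The log2 fold change was -2.36 (SE 0.07, adjusted p = 5.89e-11), a 5.13-fold loss, and each of the 3 KO libraries lay below each control. The protein-coding transcript Yme1l1-201 carried 98.8% of the gene's estimated counts in the control and 93.8% in the KO. In the other pair of groups Yme1l1 had 19 to 95 counts per library, 6.18 ± 3.31 CPM (SD, n = 4) in quiescent and 3.49 ± 1.11 CPM (SD, n = 4) in proliferating cells. That rise (log2 fold change 0.85, SE 0.35, adjusted p = 0.0472) was lost under 9 alternatives (adjusted p 0.0654 to 0.152), and without quiescent replicate 2 it was 0.46 (adjusted p = 0.137). Leaving out proliferating replicate 1, 2 or 5 also ended the call (adjusted p = 0.0736, 0.112 and 0.12).

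**Figure D1:**
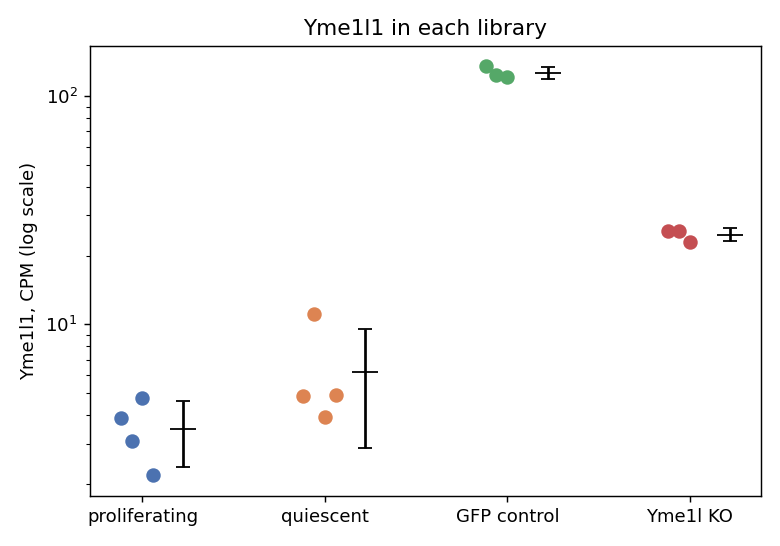
Yme1l1 in CPM (log axis) in each of the 14 libraries, 1 point per library, with the mean and SD of each group as bars. The 3 Yme1l KO libraries lie at 22.9 to 25.7 CPM and the 3 GFP controls at 121 to 135 CPM.

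The comparison of quiescent with proliferating cells asked which transcripts go with BMP4-induced quiescence. Quiescent cells had less mRNA of DNA replication genes (list median -2.45 on the log2 scale), of mitosis genes (-2.15) and of nucleotide synthesis genes (-0.97), and the growth factor response gene Egr1 fell 58.1-fold. BMP target genes such as Nog (list median 2.31) and quiescent stem cell markers such as Gfap (list median 0.49) rose. Of 12245 genes tested (n = 4 and 4), 3664 were higher and 4346 lower in quiescent cells, 1239 and 1295 of them by at least 2-fold. Scaling by library size alone moved the median gene by -0.138 on the log2 scale and gave 2823 higher and 5219 lower, so that 35.1% of calls were higher in place of 45.7%. The smallest absolute median among the lists that moved was 0.28, which is larger than that shift.

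Among the 8 largest rises in quiescent cells, Serpinf1 (ENSMUSG00000000753, chromosome 11, 75300595 to 75313527), which encodes the secreted factor PEDF, rose from 3.64 ± 0.307 to 996 ± 45.1 CPM (SD, n = 4 and 4; log2 fold change 8.09, SE 0.07, adjusted p = 1.25e-19). Gja3, a gap junction connexin, stood at 29.01 ± 5.01 CPM in quiescent cells and had no count in proliferating cells, at least 357-fold higher. Cidea, a lipid droplet protein, had 518 counts in quiescent and 3 in proliferating libraries, a ratio of 224 (95% interval 76.4 to 1090), and the ratio for the apelin receptor Aplnr was 228 (62.7 to 1890). Inpp5j (8.22, SE 0.19), Slit3 (7.38, SE 0.26) and L1cam (7.21, SE 0.28), the last a neural adhesion molecule, rose as well, as did Stum, from 0.336 to 109 CPM. Among the 8 largest falls, Egr3 had no count in quiescent cells and stood at 17.9 ± 0.66 CPM in proliferating cells, at least 167-fold lower. Egr1 (ENSMUSG00000038418, chromosome 18, 34992876 to 34998037) fell from 421 ± 32.9 to 7.09 ± 1.67 CPM (log2 fold change -5.86, SE 0.11, adjusted p = 4.04e-13). Adm (-6.23), Rgs8 (-6.12), Egr4 (-6.03), Arc (-5.56), Nptx2 (-5.48) and Vwa5b1 (-5.16) completed the 8 largest falls.

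Cell cycle genes fell nearly without exception in quiescent cells. Of the 51 DNA replication and S phase genes tested, 50 fell (median log2 fold change -2.45, camera adjusted p = 2.76e-42), and of the 47 G2/M and mitosis genes 45 fell (median -2.15, adjusted p = 9.08e-29). Both counts were the same adjusted over the list alone, and both calls held with an estimated correlation (adjusted p = 0.00902 and 0.000353). The licensing factors Cdc6 (-4.30, SE 0.16) and Mcm6 (-3.90, SE 0.09) and the chromosomal passenger proteins Aurkb (-3.06, SE 0.09) and Birc5 (-2.79, SE 0.12) were among them. Purine and pyrimidine synthesis genes fell with them, 27 of 36 lower and 3 higher (28 and 3 adjusted over the list alone; median -0.97, adjusted p = 8.77e-10, and adjusted p = 0.0279 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 3.52 (SE 0.10) on the log2 scale, and thymidine kinase Tk1 fell by 3.35 (SE 0.08). The 17 genes listed as cyclin-dependent kinase inhibitors or genes of exit from the cycle split into 7 higher and 6 lower, also adjusted over the list alone (median 0.10, mean -0.08, camera direction down, adjusted p = 0.679).

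Of 43 quiescent stem cell markers, 27 rose in quiescent cells and 11 fell (median 0.49, adjusted p = 1.65e-08), among them Sparcl1 (5.60, SE 0.21) and Id4 (3.29, SE 0.14). Of 20 markers of activated stem cells, 12 fell and 6 rose (median -1.11, adjusted p = 1.15e-05). BMP targets and feedback genes rose in 17 of 20 cases and fell in 2 (median 2.31, adjusted p = 1.07e-23). They included the BMP antagonist Nog (7.01, SE 0.09), the transcription factor Atoh8 (5.70, SE 0.10), the inhibitory SMAD gene Smad7 (4.49, SE 0.11) and Id1 (3.37, SE 0.07). Targets of receptor tyrosine kinase and ERK signalling fell in 12 of 25 cases and rose in 7 (median -0.51, adjusted p = 2.22e-05), with cyclin D1 (Ccnd1, -2.87, SE 0.04) and Myc (-2.69, SE 0.07) lower. These 4 calls held with an estimated correlation (adjusted p = 0.0333, 0.0206, 0.00262 and 0.0232). Immediate early genes fell in 12 of 20 cases and rose in 3 (median -0.83, mean -1.79, adjusted p = 1.77e-05; adjusted p = 0.0579 with an estimated correlation). The 20 Notch pathway genes, 4 higher and 12 lower, did not pass as a list (median -0.44, adjusted p = 0.292). The counts of these 6 lists were the same adjusted over the list alone.

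Lipid droplet and lipoprotein genes rose in 13 of 19 cases in quiescent cells and fell in 2 (median 0.60, adjusted p = 0.00209; adjusted p = 0.0501 with an estimated correlation), among them the cholesterol exporter Abca1 (3.54, SE 0.33) and the fatty acid binding protein gene Fabp5 (1.39, SE 0.04). Fatty acid synthesis genes rose in 17 of 25 cases and fell in 5 (median 0.32, adjusted p = 0.0235; adjusted p = 0.125 with an estimated correlation), with the elongase Elovl1 at 1.32 (SE 0.07). Peroxisomal lipid genes rose in 18 of 39 cases and fell in 2 (median 0.32, adjusted p = 0.0342; adjusted p = 0.103 with an estimated correlation), a call lost with the GC trend removed (adjusted p = 0.0507). Glycolysis and lactate genes rose in 20 of 32 cases and fell in 6 (median 0.28, adjusted p = 0.0131; adjusted p = 0.275 with an estimated correlation). Among them were the pyruvate dehydrogenase kinase Pdk4 (2.11, SE 0.23) and the lactate transporter Slc16a1 (1.22, SE 0.06). Cholesterol synthesis and uptake genes fell in 17 of 25 cases and rose in 3 (median -0.30, adjusted p = 0.0469; adjusted p = 0.186 with an estimated correlation). This sterol call was lost with RLE size factors (adjusted p = 0.0557) and without any quiescent replicate (0.0542 to 0.0629). Adjusted over the list alone the counts were the same, except that 18 fatty acid synthesis genes rose.

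Mitochondrial fatty acid oxidation did not pass as a list (22 of 43 genes higher, 7 lower, median 0.24, adjusted p = 0.256), although the coactivator Ppargc1a rose (2.13, SE 0.30) and the acyl-CoA dehydrogenase Acadl fell (-0.96, SE 0.06). The tricarboxylic acid cycle (8 of 28 higher, 9 lower, median 0.05, adjusted p = 0.59), the pentose phosphate pathway (3 of 13 higher, 4 lower, median -0.04, adjusted p = 0.816) and nuclear genes of respiratory complex I (8 of 36 higher, 9 lower, median -0.04, adjusted p = 0.971) did not pass. The nuclear genes of complexes II to V (7 of 41 higher, 11 lower, median 0, mean -0.03, camera direction up, adjusted p = 0.963) and the 13 protein-coding genes of mitochondrial DNA (median 0.22, adjusted p = 0.707) did not pass either. The smallest adjusted p among the latter genes was 0.0898, for mt-Nd2. Their list mean ran from -0.65 to 0.56 over the quiescent libraries, against -0.08 to 0.04 for complex I. A change in the genes of mitochondrial DNA could thus have been missed. Mitochondrial protein import genes fell in 25 of 33 cases (median -0.37, adjusted p = 0.0235; adjusted p = 0.234 with an estimated correlation), including the translocase subunit Timm50 (-1.24, SE 0.06). Mitochondrial ribosomal protein genes fell in 60 of 77 cases and rose in 2 (median -0.39, adjusted p = 0.00355; adjusted p = 0.306 with an estimated correlation), including Mrps27 (-1.12, SE 0.07). The mitochondrial protease and dynamics genes (8 of 29 higher, 12 lower, median 0.08, mean -0.02, camera direction down, adjusted p = 0.707) and the mitochondrial stress genes (1 of 16 higher, 9 lower, median -0.37, adjusted p = 0.323) did not pass. Adjusted over the list alone the counts were the same, except 7 complex I genes higher, 6 genes of complexes II to V higher and 61 mitochondrial ribosomal genes lower.

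Cytosolic ribosomal protein genes fell in 79 of 80 cases, and in 80 adjusted over the list alone (median -0.62, adjusted p = 1.65e-16; adjusted p = 0.234 with an estimated correlation), with Rpl27a at -0.97 (SE 0.05). Folate one-carbon and serine genes fell in 17 of 26 cases and rose in 3, 18 and 3 adjusted over the list alone (median -0.75, adjusted p = 0.000103; adjusted p = 0.103 with an estimated correlation), with the folate enzymes Shmt1 (-3.23, SE 0.11) and Tyms (-2.45, SE 0.13) lower. Lysosome and autophagy genes rose in 36 of 44 cases and fell in 3, 37 and 3 adjusted over the list alone (median 0.48, adjusted p = 5.25e-07; adjusted p = 0.16 with an estimated correlation). The lysosomal cholesterol transporter Npc1 (1.36, SE 0.05) and the protease cathepsin L (Ctsl, 1.13, SE 0.04) were among them. Matrix and adhesion genes rose in 25 of 44 cases and fell in 14, the same adjusted over the list alone (median 0.51, adjusted p = 0.000372; adjusted p = 0.103 with an estimated correlation). Integrin beta 3 (Itgb3) rose by 5.85 (SE 0.16), and the brain proteoglycan neurocan (Ncan) rose by 4.61 (SE 0.05) and took 6.50% to 7.16% of all counts in the quiescent libraries. NRF2 and antioxidant genes rose in 20 of 33 cases and fell in 8, 21 and 8 adjusted over the list alone (median 0.43, adjusted p = 0.0267; adjusted p = 0.413 with an estimated correlation). The glutathione synthesis gene Gclc rose from 54.7 ± 3.77 to 134 ± 7.93 CPM and glutathione reductase (Gsr) fell (-1.60, SE 0.07).

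Stress lists other than these did not pass in quiescent cells. They were the integrated stress response (12 of 41 higher, 24 lower, median -0.36, adjusted p = 0.0573), p53 targets (8 of 29 higher, 7 lower, median 0.14, mean -0.03, camera direction down, adjusted p = 0.757), the interferon response (6 of 22 higher, 4 lower, median 0.17, adjusted p = 0.688), NF-kB and cytokine genes (3 of 11 higher, 7 lower, median -0.56, mean -0.33, camera direction up, adjusted p = 0.802) and the hypoxia response (14 of 23 higher, 5 lower, median 0.35, adjusted p = 0.0701). The integrated stress response passed with no filter on low counts (median -0.49, adjusted p = 0.00741), with a replicate block (adjusted p = 0.0451) and without proliferating replicate 1 or 4 (adjusted p = 0.04 and 0.0425). These counts were the same adjusted over the list alone.

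Markers of other cell types moved in part. Astrocyte markers rose in 14 of 25 cases and fell in 6, 15 and 6 adjusted over the list alone (median 0.49, adjusted p = 0.0483; adjusted p = 0.133 with an estimated correlation). Gfap rose by 2.78 (SE 0.10) and S100b by 2.54 (SE 0.07), and both also count as quiescent stem cell markers. The astrocyte call was lost with the GC trend removed (adjusted p = 0.0611) and without proliferating replicate 5 (adjusted p = 0.0551). Oligodendrocyte markers (6 of 16 higher, 5 lower, median 0.30, adjusted p = 0.605), neuroblast markers (6 of 14 higher, 6 lower, median 0.05, mean -0.43, camera direction up, adjusted p = 0.688) and vessel and fibroblast markers (4 of 7 higher, 1 lower, median 1.56, adjusted p = 0.0701) did not pass. The endothelial receptor Kdr rose (2.29, SE 0.22) and smooth muscle actin Acta2 fell (-1.46, SE 0.24). The microglia markers Tmem119 (5.01, SE 0.63, at 4.06 ± 1.22 CPM) and Lyz2 (3.54, SE 0.37) rose. Tmem119 had counts in proliferating replicate 1 and in 0 of the other 3, so that the size of its rise rests on 1 library, and Cd68 (-0.67, adjusted p = 0.0911) was not called. Of 3 ependymal markers 2 fell, Foxj1 (-0.33, SE 0.07, adjusted p = 0.0564 with the GC trend removed) and Rarres2 (-1.46). These counts were the same adjusted over the list alone. The only sex-chromosome markers tested were 4 Y-linked genes, of which Kdm5d rose (0.81, adjusted p = 0.00628), and Xist was below the expression filter.

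The comparison of Yme1l KO with GFP control cells asked which transcripts go with loss of the protease. KO cells had less mRNA of cell cycle genes, of cholesterol synthesis genes and of ribosomal protein genes. They had more mRNA of p53 target genes such as Cdkn1a, of lysosomal genes and of the cholesterol exporter Abca1. These list calls (cell cycle, sterol, p53 and lysosome at adjusted p = 0.343, cytosolic ribosomal at adjusted p = 0.356) were lost with an estimated correlation, with which camera called 0 of the 38 lists (1 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 34. Correlation between members does not account for every lost call. The lipid droplet list and the mitochondrial protease list lost theirs at estimated correlations of -0.002 and -0.009, below the preset 0.01. Of 12625 genes tested (n = 3 and 3), 3201 were higher and 3308 lower in the KO, 399 and 261 of them by at least 2-fold. Of the 6509 called genes, 6386 had no overlap between the groups. With 3 libraries against 3, 10% of unselected genes separate by chance. That rate does not apply to genes called on these same libraries, so their separation adds no support. KO replicate 3 stood apart on the first principal component (41 against 21 and 18.6), and without it 3104 genes were higher and 3284 lower.

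Among the 8 largest rises, Abca1 (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895) went from 107 ± 3.91 to 438 ± 83 CPM (SD, n = 3 and 3; log2 fold change 2.03, SE 0.14, adjusted p = 4.8e-05). The histone gene H2ac19, which shares near-identical sequence with paralogs, rose by 2.19 (SE 0.26). Tmem182 (1.99, SE 0.20), the acetylcholinesterase gene Ache (1.94, SE 0.26), Svop (1.93, SE 0.12) and the thioredoxin-interacting protein gene Txnip (1.85, SE 0.19) rose as well. Ackr4 (1.84, SE 0.17) lies within the span of Acad11 on the opposite strand, and Acad11 also rose (0.85, SE 0.09). Rab43 (2.09, SE 0.59, adjusted p = 0.0337) lies within a predicted gene on the same strand that fell, and its call was lost under 8 alternatives (adjusted p 0.0512 to 0.124). After Yme1l1 the largest falls were in Draxin, an axon guidance factor (-1.92, SE 0.17), Spata13 (-1.87, SE 0.20), Zcchc12 (-1.85, SE 0.18), Egr3 (-1.80, SE 0.18), Aunip (-1.55, SE 0.23), Rcor2 (-1.44, SE 0.13) and Eme1 (-1.40, SE 0.16).

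Every tested cell cycle gene of the lists fell in the KO. All 52 DNA replication and S phase genes were lower (median -0.97, camera adjusted p = 4.96e-25; adjusted p = 0.343 with an estimated correlation), and so were all 53 G2/M and mitosis genes (median -1.03, adjusted p = 8.39e-25; adjusted p = 0.343 with an estimated correlation). The DNA polymerase gene Pold1 (-1.22, SE 0.12), Aurka (-1.27, SE 0.17) and the kinetochore gene Ndc80 (-1.22, SE 0.11) were among them. Mean changes of the S phase list were -0.83, -0.78 and -1.32 in KO replicates 1, 2 and 3. Nucleotide synthesis genes fell in 27 of 36 cases and rose in 3 (median -0.59, adjusted p = 5.75e-11; adjusted p = 0.343 with an estimated correlation), with Rrm2 at -1.19 (SE 0.17) and Tk1 at -1.16 (SE 0.18). One-carbon genes fell in 19 of 26 cases and rose in 2 (median -0.51, adjusted p = 3.22e-07; adjusted p = 0.343 with an estimated correlation). The mitochondrial folate enzymes Shmt2 (-1.03, SE 0.13) and Mthfd2 (-0.95, SE 0.15) were among them. These counts were the same adjusted over the list alone.

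p53 target genes rose in 28 of 32 cases and fell in 2, 29 and 2 adjusted over the list alone (median 0.72, adjusted p = 7.68e-17; adjusted p = 0.343 with an estimated correlation). The cell cycle inhibitor p21 (Cdkn1a, ENSMUSG00000023067, chromosome 17, 29309950 to 29319701) rose from 293 ± 5.18 to 720 ± 116 CPM (log2 fold change 1.29, SE 0.10, adjusted p = 2.82e-05). The carbonyl reductase gene Dcxr (1.49, SE 0.12), the pro-apoptotic gene Pmaip1 (1.45, SE 0.12) and the stress cytokine gene Gdf15 (1.43, SE 0.17) rose as well. The mean change of the list was 0.66, 0.65 and 0.91 in KO replicates 1, 2 and 3. The mixed list of cyclin-dependent kinase inhibitors and genes of exit from the cycle rose in 12 of 18 cases and fell in 4, the same adjusted over the list alone (median 0.34, adjusted p = 0.00596, and adjusted p = 0.343 with an estimated correlation). Tob1 was higher (0.98, SE 0.11) and the inhibitor gene Cdkn2c lower (-0.78, SE 0.09). Of 10 genes whose symbol starts with Cdkn, 3 rose and 5 fell (median -0.37, camera adjusted p = 0.527 over 148 symbol families). The list therefore does not show a rise of the inhibitors as a class.

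Cholesterol synthesis and uptake genes fell in 22 of 25 cases and rose in 1, Lpin1 (24 and 1 adjusted over the list alone; median -0.89, adjusted p = 8.98e-15; adjusted p = 0.343 with an estimated correlation). Lanosterol synthase (Lss, -1.17, SE 0.09), Acat2 (-1.17, SE 0.08) and farnesyl diphosphate synthase (Fdps, -1.17, SE 0.15) led the falls, and the list means were -0.68, -0.62 and -0.97 in KO replicates 1, 2 and 3. Mitochondrial fatty acid oxidation genes rose in 19 of 43 cases and fell in 3, the same adjusted over the list alone (median 0.22, adjusted p = 0.00232, and adjusted p = 0.343 with an estimated correlation), with Acad12 (0.95, SE 0.13) higher. Peroxisomal lipid genes rose in 11 of 37 cases and fell in 3, 11 and 2 adjusted over the list alone (median 0.17, adjusted p = 0.0298; adjusted p = 0.343 with an estimated correlation), with the carnitine acyltransferase Crot higher (1.02, SE 0.07). Lipid droplet and lipoprotein genes rose in 9 of 17 cases and fell in 3, 10 and 3 adjusted over the list alone (median 0.46, adjusted p = 0.00352; adjusted p = 0.343 with an estimated correlation), with apolipoprotein E (Apoe) at 1.18 (SE 0.17). Fatty acid synthesis (6 of 23 higher, 12 lower, 15 lower adjusted over the list alone, median -0.18, adjusted p = 0.0805), glycolysis (14 of 30 higher, 7 lower, median 0.16, adjusted p = 0.104), the pentose phosphate pathway (1 of 12 higher, 5 lower, median -0.10, adjusted p = 0.12) and the tricarboxylic acid cycle (3 of 28 higher, 8 lower, median -0.03, adjusted p = 0.274) did not pass. For the last 3 the counts were the same adjusted over the list alone. Fatty acid synthesis passed with no filter on low counts (median -0.17, adjusted p = 0.0386).

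Of the mitochondrial lists, ribosomal protein genes fell in 42 of 77 cases, 44 adjusted over the list alone (median -0.24, adjusted p = 2.28e-05; adjusted p = 0.343 with an estimated correlation), with Mrps18b at -0.81 (SE 0.11). Protein import and chaperone genes fell in 19 of 33 cases (median -0.24, adjusted p = 0.000177; adjusted p = 0.343 with an estimated correlation), with the chaperonin Hspd1 at -0.76 (SE 0.07). The mitochondrial stress genes, which include Yme1l1, fell in 11 of 16 cases and rose in 1, Atf5 (2 adjusted over the list alone; median -0.21, adjusted p = 0.00189; adjusted p = 0.343 with an estimated correlation). The protease and dynamics list, which also includes Yme1l1, fell in 12 of 29 cases and rose in 3 (median -0.16, adjusted p = 0.0375; adjusted p = 0.343 with an estimated correlation). That call was lost without KO replicate 1 (median -0.05, adjusted p = 0.0667) and without KO replicate 3 (adjusted p = 0.0543). The fusion GTPase Opa1 (0.02, adjusted p = 0.789), the protease Oma1 (-0.02, adjusted p = 0.891) and the fission GTPase Dnm1l (-0.01, adjusted p = 0.846), read after their values were seen, were not called. Genes of mitochondrial DNA rose in 7 of 13 cases, among them mt-Nd5 (0.46, SE 0.05; 0.43, adjusted p = 0.141, with all libraries in one fit), and fell in 1, mt-Nd6 (-0.73, SE 0.11), which overlaps mt-Nd5 on the opposite strand. That list (median 0.28, adjusted p = 0.0379; adjusted p = 0.37 with an estimated correlation) was lost without GFP control replicate 3, KO replicate 1 or KO replicate 3 (adjusted p = 0.0507, 0.0633 and 0.0551). Complex I (7 of 36 higher, 1 lower, 5 and 0 adjusted over the list alone, median 0.04, adjusted p = 0.421) and complexes II to V (11 of 41 higher, 3 lower, median 0.05, adjusted p = 0.169) did not pass. Counts of the other lists here were the same adjusted over the list alone.

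Lysosome and autophagy genes rose in 37 of 44 cases and fell in 0, 38 and 0 adjusted over the list alone (median 0.47, adjusted p = 1.98e-15; adjusted p = 0.343 with an estimated correlation), with cathepsin F (Ctsf, 1.25, SE 0.13) and the autophagy gene Wipi1 (0.95, SE 0.09) higher. Cytosolic ribosomal protein genes fell in 77 of 80 cases, 78 adjusted over the list alone (median -0.31, adjusted p = 9.97e-15; adjusted p = 0.356 with an estimated correlation), with Rpl14 at -0.51 (SE 0.06). Integrated stress response and ATF4 target genes fell in 25 of 42 cases and rose in 8, 26 and 9 adjusted over the list alone (median -0.41, adjusted p = 0.00496; adjusted p = 0.376 with an estimated correlation). The glutamine transporter Slc1a5 fell (-1.31, SE 0.20), and Gdf15 was among those that rose. Interferon genes rose in 12 of 24 cases and fell in 2, 13 and 2 adjusted over the list alone (median 0.46, adjusted p = 0.0189; adjusted p = 0.37 with an estimated correlation), with the peptide transporter Tap1 at 1.16 (SE 0.12). The interferon call was lost without KO replicate 3 (median 0.35, adjusted p = 0.102), and the list mean was 0.32, 0.39 and 0.67 in KO replicates 1, 2 and 3. Antioxidant genes rose in 17 of 32 cases and fell in 7, the same adjusted over the list alone (median 0.16, adjusted p = 0.0467; adjusted p = 0.352 with an estimated correlation), with superoxide dismutase Sod3 at 1.05 (SE 0.08). The antioxidant call was lost without GFP control replicate 2 or 3 (adjusted p = 0.0676 and 0.0507). NF-kB and cytokine genes (3 of 10 higher, 1 lower, median 0.24, adjusted p = 0.597), hypoxia genes (12 of 22 higher, 3 lower, median 0.25, adjusted p = 0.12) and matrix genes (15 of 41 higher, 9 lower, median 0.15, adjusted p = 0.171) did not pass, with the same counts adjusted over the list alone.

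Quiescent stem cell markers rose in 20 of 43 cases and fell in 9, 22 and 10 adjusted over the list alone (median 0.29, adjusted p = 0.00352; adjusted p = 0.37 with an estimated correlation), with the carboxypeptidase Cpe higher (1.14, SE 0.10) and Vcam1 lower (-0.94, SE 0.17). Targets of receptor tyrosine kinase and ERK signalling rose in 16 of 24 cases and fell in 4, the same adjusted over the list alone (median 0.29, adjusted p = 0.00393; adjusted p = 0.343 with an estimated correlation). The phosphatase Dusp4 rose (1.07, SE 0.06), while the transcription factors Egr1 (-1.12, SE 0.08) and Egr2 (-1.35, SE 0.15) fell. Markers of activated stem cells (5 of 19 higher, 8 lower, 5 and 9 adjusted over the list alone, median -0.25, adjusted p = 0.169), BMP targets (7 of 19 higher, 3 lower, 7 and 4 adjusted over the list alone, median 0.16, adjusted p = 0.103), Notch genes (4 of 18 higher, 4 lower, median 0, mean -0.12, camera direction up, adjusted p = 0.842) and immediate early genes (5 of 20 higher, 7 lower, median -0.14, adjusted p = 0.211) did not pass. BMP targets passed without KO replicate 3 (median 0.06, adjusted p = 0.0426). Astrocyte (13 of 22 higher, 5 lower, 14 and 6 adjusted over the list alone, median 0.29, adjusted p = 0.0672), oligodendrocyte (6 of 13 higher, 0 lower, median 0.18, adjusted p = 0.0559) and neuroblast markers (4 of 16 higher, 6 lower, median 0.01, mean -0.02, camera direction up, adjusted p = 0.921) did not pass. The astrocyte list passed with no filter on low counts (adjusted p = 0.0366) and without KO replicate 2 or 3 (adjusted p = 0.0456 and 0.0126). The oligodendrocyte list passed with a replicate block (adjusted p = 0.0467) and without KO replicate 2 or 3 (adjusted p = 0.0391 and 0.0241). The microglia markers P2ry12 (0.52, adjusted p = 0.0923) and Cd68 (adjusted p = 0.253) were not called. Of 3 vessel markers Tek rose (0.85, SE 0.15). The ependymal markers Hydin (0.21), Ccno (-0.71) and Foxj1 (0.28, adjusted p = 0.0852) were not called, and Foxj1 passed with no filter on low counts (0.28, adjusted p = 0.0482) and without KO replicate 2 (0.37, adjusted p = 0.0342). Of the 4 Y-linked markers Eif2s3y rose (0.27, adjusted p = 0.00294). Counts not given for the list alone were the same adjusted over the list alone.

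**Figure D2:**
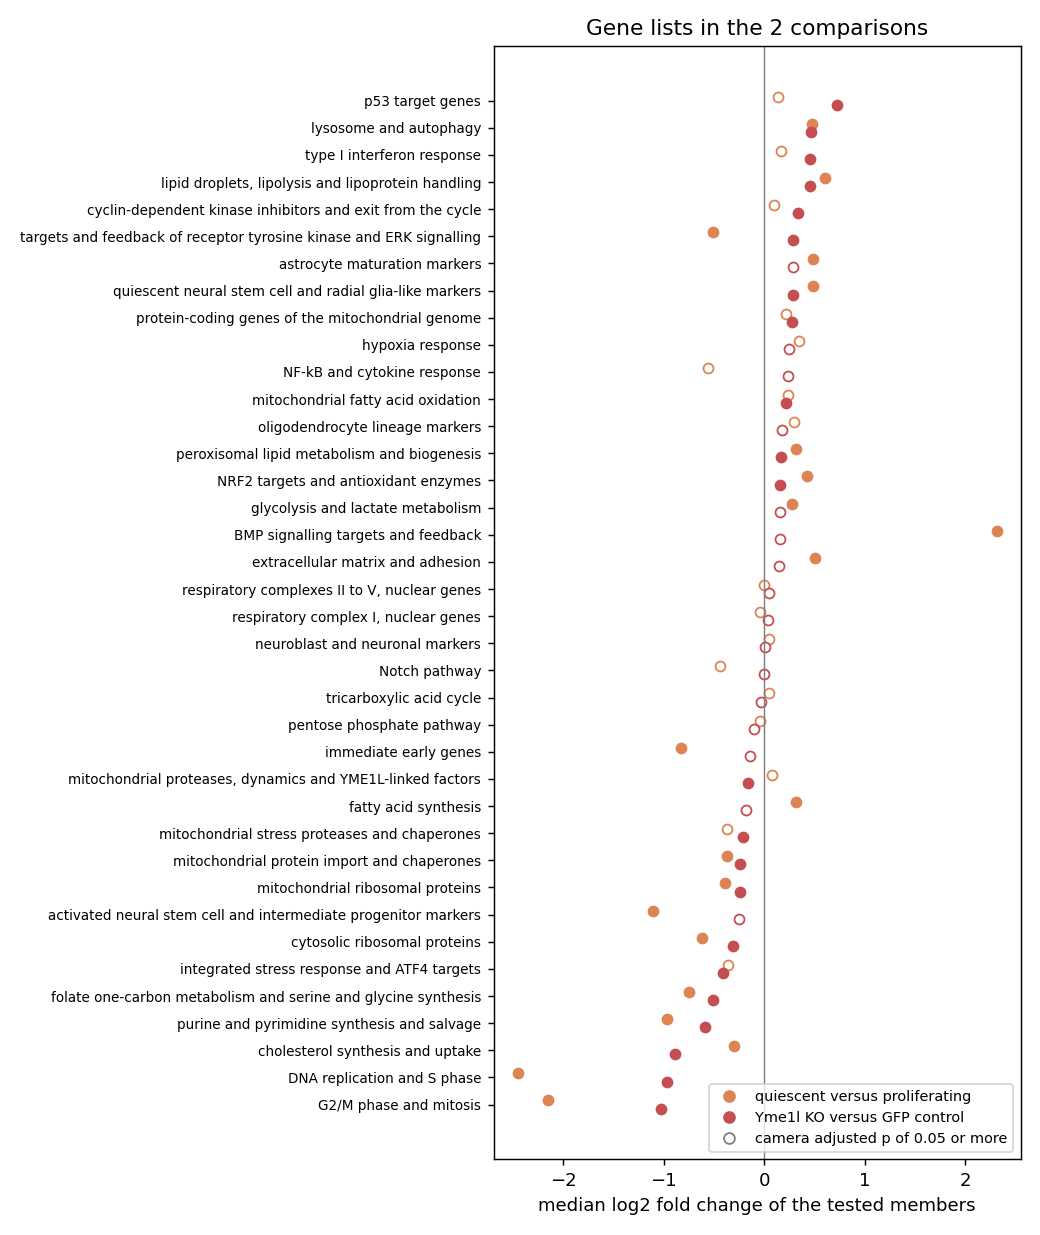
Median log2 fold change (horizontal axis) of the tested members of each gene list in both comparisons, with open circles for lists at a camera adjusted p of 0.05 or more. The p53 targets lie at 0.72 in the Yme1l KO and at 0.14 in quiescent cells, and the S phase list lies at -0.97 and -2.45.

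A last comparison asked whether genes that follow quiescence also follow loss of Yme1l. Of genes higher in quiescent cells by at least 2-fold, 983 were tested in the KO, where 514 were higher and 90 lower (median log2 fold change 0.31, camera p = 5.09e-14, adjusted p = 5.09e-14 over both sets; p = 0.0553, adjusted p = 0.0593, with an estimated correlation). Of those lower in quiescent cells, 1188 were tested, of which 109 were higher and 790 lower in the KO (median -0.59, camera p = 1.07e-25, adjusted p = 2.14e-25; p = 0.0593, adjusted p = 0.0593, with an estimated correlation). Ranked by the smaller of their 2 fold changes among genes called in both comparisons at a mean of at least 5 CPM, predicted genes left out, Abca1, the potassium channel gene Kcnt1 (1.89 in quiescent cells and 1.82 in the KO), Tcp11l2 (1.99 and 1.58), the metalloproteinase gene Mmp19 (1.74 and 1.57) and the receptor kinase gene Mertk (2.19 and 1.52) led the genes that rose in both. Egr3, Zcchc12 (-3.51 and -1.85), Rcor2 (-3.21 and -1.44), the nuclease gene Eme1 (-3.10 and -1.40) and Atp10a (-1.77 and -1.36) led those that fell in both by the same ranking. Opposite changes were fewer. Slc35f1 (1.96 and -1.06), Igsf3 (2.28 and -1.04), Abcg2 (1.08 and -1.01), Lrp8 (1.10 and -0.97) and Nr2c2ap (2.46 and -0.96) rose in quiescent cells and fell in the KO, while Klhdc7a (-2.26 and 1.68), Ggt5 (-1.43 and 1.25), Jade2 (-1.66 and 1.12) and Clic5 (-1.04 and 1.16) did the reverse.

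Among 11477 genes tested in both comparisons, 1703 were called higher in both, against 872.3 for independent lists, and 2117 lower in both, against 1152.4. Genes called in opposite directions numbered 286 and 449, against 921.3 and 1091.1. Pearson's r of the log2 fold changes across these genes was 0.49 and Spearman's rho was 0.50. The 2 comparisons share no library.

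**Figure D3:**
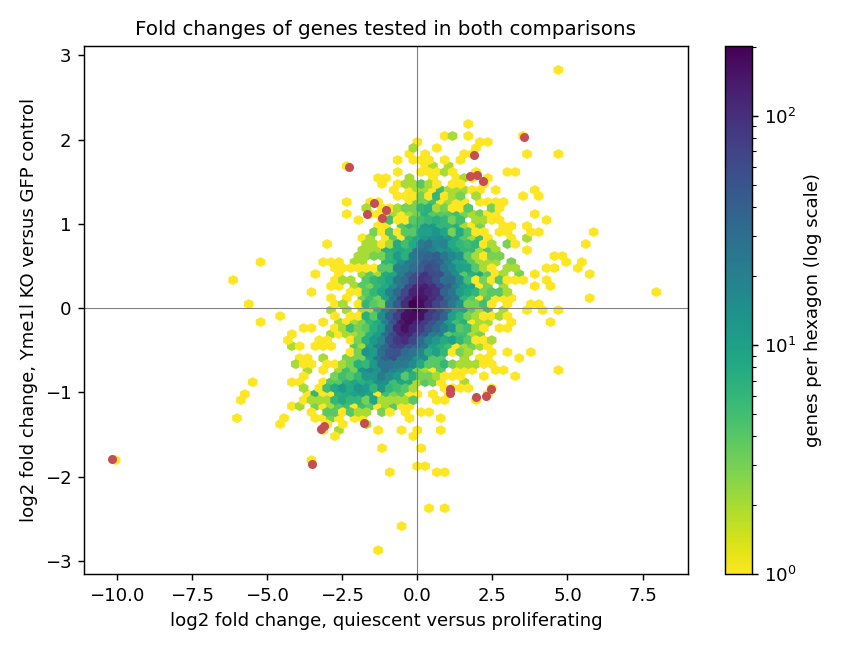
Log2 fold change in the Yme1l KO (vertical axis) against that in quiescent cells (horizontal axis) for genes tested in both comparisons, with the colour of each hexagon giving the number of genes on a log scale and red points marking the 20 genes with the largest shared or opposite changes. Pearson's r across the 11477 genes is 0.49.

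GC content set the 2 tables apart. Across 10500 protein-coding genes, the log2 ratio of proliferating to GFP control CPM correlated with the GC content of the transcript (Pearson's r 0.71, Spearman's rho 0.77), and genes are not independent replicates. It also correlated with log2 transcript length (Pearson's r -0.37), and GC content and length were not separated. The median log2 ratio was -3.39 in genes under 40% GC and 1.11 in genes over 60%. Yme1l1, at 38% GC, stood at 3.49 CPM in proliferating and at 127 CPM in GFP control cells. Within the tables the same medians were 0.34 and -0.22 for quiescent over proliferating cells and -0.04 and 0.10 for Yme1l KO over GFP control. No single gene's level was tested across the tables. The ribosomal RNA gene Rn18s took 1.22 to 2.53% of counts in the quiescent and proliferating libraries and 0.25 to 0.532% in the GFP control and KO libraries, and genes of mitochondrial DNA took 0.313 to 0.588% and 3.5 to 4.39%. Rn18s was also higher in each quiescent library (1.81 to 2.53%) than in each proliferating one (1.22 to 1.7%), and the cause was not tested.

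**Figure D4:**
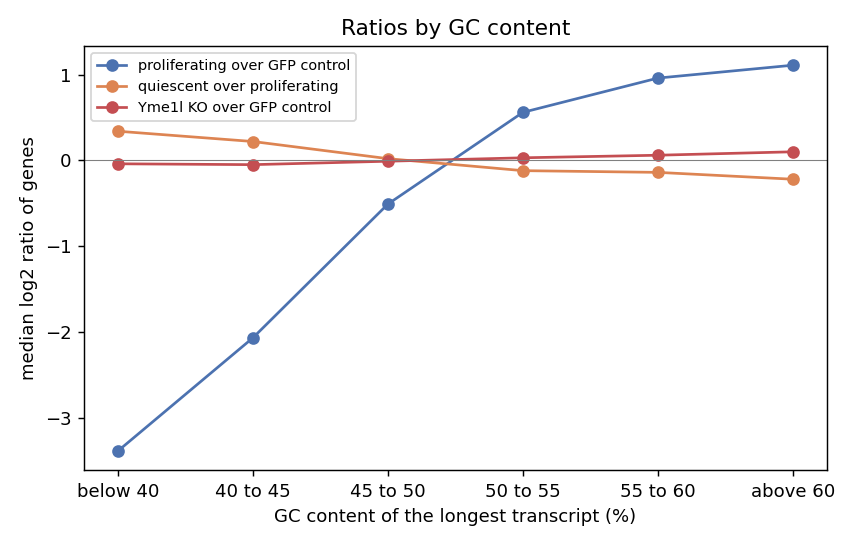
Median log2 ratio of genes (vertical axis) by bins of GC content in percent (horizontal axis) for 3 pairs of groups, 1 point per bin. Proliferating over GFP control runs from -3.39 to 1.11, and the pairs within a table stay between -0.22 and 0.34.

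The authors' deposited test tables call fewer genes. For the quiescent comparison their table, coded as proliferating minus quiescent, calls 3591 genes higher and 3627 lower in quiescent cells, and 6656 of the 6658 genes called both there and here had the same direction, while 1352 genes were called here only. For the KO it calls 2086 higher and 2356 lower, and all 4334 genes called in both had the same direction, while 2175 were called here only. Yme1l1 is at -2.08 in the deposited KO table and, as proliferating minus quiescent, at -0.95 (adjusted p = 0.0283) in the other, which calls it higher in quiescent cells.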

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

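The depth test and the tests that removed the trend with GC content were chosen only after their results were seen. Each measure of the 4 quiescent and the 4 proliferating libraries was compared within its group for a library far from the others, by the gap to its nearest neighbour over the range (Dixon's test at the 95% level). Of 160 such groups 9 held a library of this kind, and chance gives about 5%. Quiescent replicate 2 accounted for 5 of the 9. Its Yme1l1 level was 11.1 CPM against 3.91 to 4.88 in the others. Its Egr1 level was 9.58 CPM against 6.14 to 6.51, its Abca1 level 275 CPM against 132 to 153, and its Slc35f1 level 16.6 CPM against 7.44 to 8.46. Its AT-rich genes (under 45% GC) deviated from the mean library by 0.33 on the log2 scale, against -0.12 to -0.06 in the others. Arc had 0 CPM in quiescent replicate 3 against 0.698 to 0.808 in the others. Rgs8 stood at 17.9 CPM in proliferating replicate 2 against 15.1 to 15.5. The microglia marker Tmem119 stood at 0.422 CPM in proliferating replicate 1 against 0 in the others. The TMM factor of proliferating replicate 1 was 1.06 against 1.05 in the others.

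AT-rich transcripts, Yme1l1 among them, were low in the quiescent and proliferating libraries relative to the GFP control libraries. Lower depth was weighed by the total count, and the proliferating libraries held 0.89 of that of the controls. CPM already divides by the total, so this ratio could not decide whether depth plays a part. Loss of fragments by GC content may contribute: within 79 cytosolic ribosomal protein genes the ratio correlated with GC content at r = 0.31, which passed the bound set in advance, but its 95% bootstrap interval (-0.01 to 0.62) covered the values of the alternative, and the interval was added as a criterion after the value was seen. Library chemistry and a difference between cells with and without virus therefore cannot be told apart, because each table holds its own groups. For calls between quiescent and proliferating cells, a trend with GC content as the whole cause was argued against, since 91.3% of calls kept their direction and passed with each library's trend removed.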

How the results depend on the processing

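The GC trend removed, TPM-scaled counts and, for the quiescence sets, an estimated correlation and leaving out each quiescent or proliferating library were chosen only after results were seen. No list that passed and no named gene with a call changed direction, while the medians of some lists that did not pass crossed 0, and 1 called gene of the quiescent comparison was called the other way with TPM-scaled counts and 1 with limma on log2 TPM. The gene counts stayed within 1.5 times under every alternative except a 2-fold threshold, which by construction leaves 1239 genes higher and 1295 lower in quiescent cells and 399 and 261 in the KO. Leaving out each library gave 3379 to 4086 higher, 3738 to 4197 lower and 20 to 22 lists in quiescent cells, and 2683 to 3122, 2884 to 3284 and 20 to 24 in the KO. An estimated correlation in camera left 7 of 21 lists in quiescent cells (14 at an unadjusted p under 0.05) and 0 of 22 in the KO (1 at an unadjusted p), and fry gave 35 and 34. Some of these calls were lost at an estimated correlation below the preset 0.01, such as peroxisomal lipid genes in quiescent cells (-0.003) and lipid droplet genes in the KO (-0.002). Such losses do not show that the members vary together. The quiescence sets missed the threshold in the KO with an estimated correlation (p = 0.0553 and 0.0593), which cannot change their medians (0.31 and -0.59), while without single KO or GFP control libraries the medians ran from 0.29 to 0.34 and from -0.63 to -0.50, and r from 0.46 to 0.49. Without single quiescent or proliferating libraries they ran from 0.28 to 0.35 and from -0.61 to -0.58, and r from 0.48 to 0.50. Replicate numbers did not pair the libraries (r of same-number deviations -0.33 to -0.01 and -0.06 to 0), and a replicate block gave 2859 and 3694 genes in quiescent cells and 3063 and 3189 in the KO. Of the named genes' values, 10 lost and 1 gained a call in quiescent cells, and 9 and 2 did in the KO. The cause was not tested. Low counts limit the precision of Yme1l1 in the quiescent and proliferating libraries (19 to 95 counts), and the microglia, vessel and ependymal markers left untested stood at a mean of at most 0.867 CPM.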

Other observations

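The histone and symbol-family sets, and the tests of the p53 list against the GC trend and against quiescent cells, were chosen only after results were seen, and the removal of the GC trend was added after seeing the data. Clustered histone genes, whose mRNAs are made mainly in S phase and mostly lack a poly-A tail, rose in the KO while replication genes fell. Of 18 such genes tested 15 rose and 0 fell, the same adjusted over the list alone (median 1.31, camera adjusted p = 1.24e-05 over 4 tests of such sets; adjusted p = 0.157 with an estimated correlation), with H1f2 at 1.57 (SE 0.18) and H2bc4 at 0.71 (SE 0.08), and many share near-identical sequence. In quiescent cells 4 of 15 rose and 1 fell, 3 and 0 adjusted over the list alone. Their median there was 0.16, and the set did not pass (camera adjusted p = 0.479). H1f10 (-0.64 in the KO), a histone gene outside the clusters, was left out of the set after its value was seen. Nucleoporin genes, which encode the nuclear pore, fell in 19 of 20 cases in the KO, also adjusted over the list alone (median -0.55, adjusted p = 3.49e-08 over 148 symbol families; adjusted p = 0.538 with an estimated correlation, or 0.147 over the 4 tests above). In quiescent cells 15 fell and 1 rose, the same adjusted over the list alone (median -0.96, adjusted p = 0.000116 over 146 families; adjusted p = 0.385 with an estimated correlation, or 0.0496, which passed, over the 4 tests above), with Nup210 at -2.34 (SE 0.05) and Nup93 at 0.42 (SE 0.05). Of the Abca lipid transporter family 7 of 10 genes rose in the KO (median 0.47, adjusted p = 0.00125; adjusted p = 0.538 with an estimated correlation), and of the beta protocadherins, neural adhesion genes, 12 of 18 rose (median 0.58, adjusted p = 0.0103; adjusted p = 0.538 with an estimated correlation).

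All 35 ways of regrouping the 8 quiescent and proliferating libraries were fitted. As many called genes as the real 8010 came in 1 way, the real one. The highest other was 0 (985 at an unadjusted p under 0.05). The share of 1 in 35, the smallest possible here, argues against an arbitrary grouping of the libraries but does not exclude it. Every other split mixes quiescent with proliferating libraries, which raises the spread within groups, so few calls there were likely beforehand. The 6 KO and control libraries allow 10 splits, too few for a share under 0.05. The real split called 6509 genes and the highest other called 0 (132 at an unadjusted p under 0.05).

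The rise of p53 targets in the KO had 3 explanations weighed. A trend with GC content was argued against, since the median was 0.74 with each library's trend removed and 0.72 without. Fewer cycling cells were weighed through the quiescent comparison. The same 29 members were higher in the KO than in that comparison by a median of 0.65, in 25 of 29 cases. The two-sided sign-flip permutation p was 1e-05, the smallest that the permutations can give, although cell cycle genes fell further in quiescent cells. BMP4-induced quiescence thus came without such a rise. Those groups also differ in the factors added (BMP4 against FGF and EGF), so fewer cycling cells alone were not tested. Cre recombinase itself and loss of Yme1l cannot be told apart, because 0 libraries held Cre in cells without loxP sites. Members of the list are regulated together, so their permutation p may overstate the evidence.

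The resemblance of both comparisons was weighed against cell cycle genes alone and a trend with GC content. Without both cell cycle lists r was 0.47, and with the trend removed in both comparisons it was 0.52, against 0.49. The SD of r over single libraries was 0.034. From genes under 40% GC to genes over 60%, medians ran from 0.34 to -0.22 in quiescent cells and from -0.04 to 0.10 in the KO. Trends in opposite directions work against a positive r, so removing them could hardly have lowered it. These directions, rather than the value of 0.52, argue against the GC trend as the whole cause. Dropping the lists left 11379 of 11477 genes, so r could hardly have fallen. The value of 0.47 shows only that the listed genes do not carry r, and other genes that follow proliferation stayed in. A hypothesis that remains is that loss of Yme1l may move cells towards part of the quiescent program. List medians also differed, at 0.66 in the KO and 0.14 in quiescent cells for p53 targets, 0.29 and -0.57 for ERK targets, 0.10 and 2.21 for BMP targets and -0.18 and 0.31 for fatty acid synthesis, and only the p53 difference was tested. Cre in the KO cells and slower growth of any kind stay open, and the series holds neither Cre in cells without loxP sites nor cells matched for growth, which would decide.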
